A study of Oryza sativa Japonica Group with 15 samples.

How the data were processed

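QuantSeq 3′ mRNA-Seq libraries, which count reads from the 3′ ends of transcripts, were made from 2 µg of root RNA of rice seedlings, per the labels' protocols. Seedlings were transplanted 5 days after germination and grown at 28 °C with 12 h of light, leaves were sprayed with the compound in 0.1% Tween 20, and the roots of 4 plants were pooled per sample, per the labels' protocols. The 15 samples fall into 5 groups of 3 separate pools, each sample assigned by its own label. The deposited values are a signal, read counts per gene that the authors divided by 1 size factor per library, as the normalised counts of DESeq2 are, per the submitters' processing notes and the values themselves. FastQC 0.11.8, Trimmomatic 0.38, STAR 2.6.1d and DESeq2 are named in the submitters' processing notes. The genome build, the annotation and the strand setting are not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners, and members of gene families with near copies (PAL, C4H, WRKY, chitinase and PR10 genes) may share reads. 

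Whole reads were recovered from the steps between low values: 100% of the values in each library were whole multiples of 1 read within a tolerance of 0.1. Size factors ran from 0.620 to 1.53 and recovered totals from 4130194 to 9480830 reads. Of 36747 features, 35667 carried a RAP identifier of rice, 852 were noncoding RNA identifiers and 228 others were 0 in every library. A count of 0 was taken to allow up to 3 reads per library, which is 1.96 to 4.84 normalised reads. The reads carry no molecular identifiers, and the floors cover counting error only. Intervals of fold changes come from the main test described below and rest on the spread between replicates. No pair of replicates was alike within sampling noise (chi-square per degree of freedom 3.71 to 29.2 on the recovered reads).

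The main test was limma 3.58.1 with a trend (R 4.3.3) on log2(normalised count + 1) of the 18316 genes with a mean of at least 5, with all 15 libraries in 1 fit, group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The comparisons were each inducer group with mock, PA2x with PA1x, PA1x with ASM, PA1x with BABA and ASM with BABA, with a moderated F test over the 5 groups. Gene lists (18) were tested with camera at a preset correlation of 0.01, adjusted over 72 tests, and with the correlation estimated per list, with which no list passed in the 4 comparisons with mock. A second planned test, fry in its directional form, asks whether the members shift in 1 direction, not whether they change more than other genes. Adjusted over the same 72 tests, the salicylate and defence WRKY list passed with fry in all 4. Its adjusted p were 0.011, 0.00145, 0.0201 and 0.00226 for BABA, ASM, PA1x and PA2x. With ASM the jasmonate, aquaporin and reference gene lists passed too (fry adjusted p = 0.0431 for each), and no other list passed. List tests of the 4 direct comparisons were added after the data were examined and adjusted over 18 lists each, and they were not refitted with libraries left out. The design, the tests, the lists, the other alternatives and the rule for named genes were fixed before the data were examined. Members were also counted after Benjamini-Hochberg adjustment over the members of their own list in 1 comparison, printed as adjusted over the list alone. That count was not in the fixed design and is not corrected over the lists and comparisons. That rule took, for each comparison with mock, the 8 highest and 8 lowest genes by log2 fold change past the threshold whose groups did not overlap and whose mean was at least 20, and 5 and 5 for direct comparisons. It also took up to 4 called members per list and comparison, WRKY45, NPR1, PR1a, PR1b, AS1 and every PAL and C4H gene. Of the first kind, the text prints extreme genes only, so that the gene said to rise or fall most is the one of these, and CPS4, IRT1, YSL15 and GS1;2 were chosen after their values were seen. The result of 1 list gene is not reported here.

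The file gives identifiers without gene names. The RefSeq gene table of assembly ASM3414082v1 holds 1 of the file's identifiers, so it could not name the genes. The names printed here come from the fixed lists, which pair RAP identifiers with names from general knowledge, and each name is printed with its identifier. Of 210 list members 207 were in the file. For 124 members a namesake in the RefSeq table lay on the same chromosome in a matching order. Chance places a single namesake on the same chromosome for 8.33% of names, a figure that leaves the order out. Where several namesakes lay there, the one nearest the position expected from other members was taken, which favours a matching order. For 80 members, among them WRKY45, PR1a, MYC2, AS1 and all PAL and C4H genes, the table had no namesake, so those names rest on the lists alone. The 4 members on another chromosome were left out, 2 whose order differed are printed as identifiers, and 203 members were used. The rule for this check was changed once after its output was seen, which affected labels and no test. Further lists defined by words in gene descriptions were not used here, because the table has no descriptions.

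Overlaps of calls were set beside 100 simulations of unchanged groups. Alternatives were pseudocounts of 0.5 and 5, no filter (28977 genes) and a mean of at least 20 (14036 genes), TMM scaling, the replicate number as a block, fits of only the 6 libraries compared, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Alternatives added after the data were examined were the first within-group component as a covariate, the position of each library on it with group means included as a covariate, reads thinned to 4130194 per library, and leaving out all libraries numbered 3. The count tests called 69 (edgeR) and 201 (DESeq2) genes for BABA, 901 and 1046 for ASM, 711 and 836 for PA1x and 165 and 375 for PA2x. The tests were tested on simulated data: for ASM against mock, with 18188 genes, limma recovered 54.6% of genes changed 2-fold and 88% of those changed 4-fold, with 7 false calls of 148 (4.73%). There edgeR made 9 false calls of 152 (5.92%) and DESeq2 13 of 155 (8.39%), above the 0.05 of the adjustment. With nothing changed, for PA1x against mock, limma made 0 calls, as did edgeR and DESeq2. The simulation drew each gene independently, without the axis that the real replicates share. Its false-call rates may therefore not hold for the deposited data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.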

Results

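Root transcriptomes were measured in rice seedlings (Oryza sativa Japonica Group, cultivar Kitaake) whose leaves had been sprayed with 1 of 3 resistance inducers, compounds that raise a plant's readiness for defence. Piperonylic acid (PA) inhibits cinnamate 4-hydroxylase, an enzyme of the phenylpropanoid pathway. Acibenzolar-S-methyl (ASM) is a functional analogue of salicylic acid, and beta-aminobutyric acid (BABA) is an amino acid that is not built into proteins. There were 5 groups of 3 libraries, each library from the pooled roots of 4 plants. Mock, BABA (3.5 mM), ASM (250 µM) and PA1x plants (PA at 300 µM) were sprayed on day 13 after transplantation, PA2x plants (PA at 300 µM) on days 7 and 13, and roots were taken on day 14. The labels give the mock group a spray on day 13 only, so PA2x had no mock group with its own schedule. Doses differed between compounds, and each comparison between them is one of compound and dose together. Recovered read totals ran from 7392515 to 9480830 in mock, 4130194 to 6717016 in BABA, 6066946 to 6911751 in ASM, 6576300 to 8364583 in PA1x and 4851344 to 6815702 in PA2x. Of 36747 features, 28977 had a read in at least 1 library, and 18316 with a mean normalised read count of at least 5 were tested.

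Expression of 2227 of the 18316 genes varied over the 5 groups at an adjusted p under 0.05 (limma's moderated F test). Against mock, ASM changed 830 genes, PA1x 646, PA2x 170 and BABA 46. ASM, PA2x and BABA mostly raised expression, with 600, 140 and 40 genes higher and 230, 30 and 6 lower. PA1x mostly lowered it, with 73 genes higher and 573 lower. These counts rest on 1 estimate of spread per gene over all 5 groups. With only the 6 libraries compared in each fit, PA1x had 856 genes, ASM 394, PA2x 23 and BABA 10. The order of ASM and PA1x thus depends on the fit. Nearly all called genes had 3 treated values on the same side of the 3 mock values, 825 of the 830 for ASM and all 646, 170 and 46 for the others. Chance alone gives that separation for 10% of genes, and 19.8% of all tested genes showed it for ASM, 21.1% for PA1x, 15.1% for PA2x and 14.9% for BABA.

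**Figure D1:**
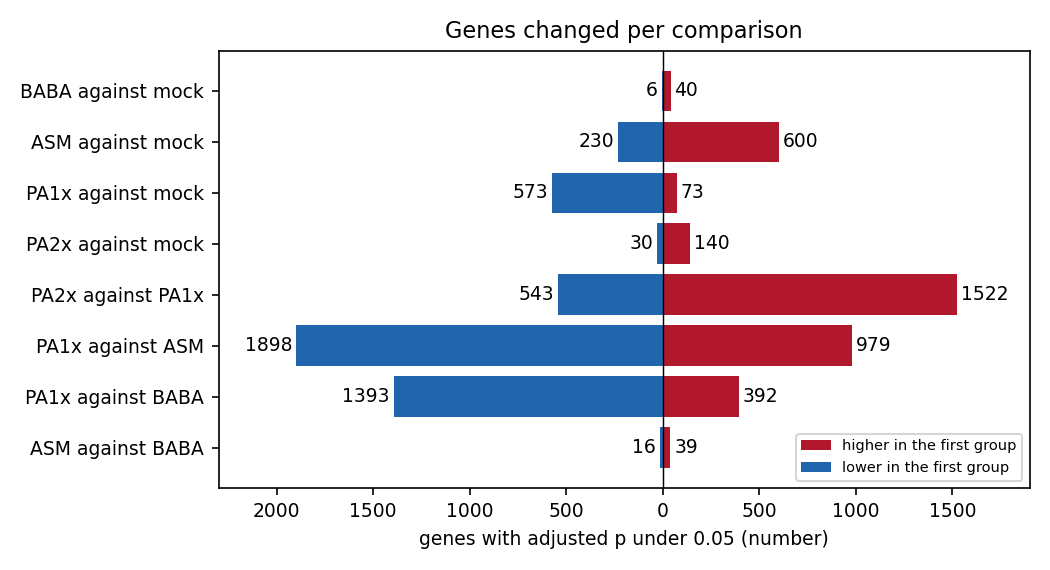
Number of genes with an adjusted p under 0.05 in each of the 8 comparisons, drawn to the right when higher and to the left when lower in the group named first. PA1x against mock has more genes lower (573) than higher (73), the reverse of the other comparisons with mock, and PA1x against ASM has the most genes in all (979 higher, 1898 lower).

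The comparison of BABA with mock asked which root genes respond to a leaf spray of this inducer. WRKY76 (Os09g0417600) and WRKY62 (Os09g0417800), neighbouring transcription factor genes that act on defence, rose 2.77-fold and 2.44-fold. WRKY76 went from 107 ± 10.3 to 297 ± 12.0 normalised reads (mean ± SD, n = 3; log2 fold change 1.47 ± 0.13 SE, adjusted p = 0.000118), and WRKY62 from 26.8 ± 2.26 to 66.6 ± 3.22 (1.29 ± 0.21, adjusted p = 0.0173). JAR1 (Os05g0586200), which makes the active isoleucine conjugate of jasmonate, rose 1.56-fold (0.64 ± 0.11, adjusted p = 0.0217). No other list member was called. The salicylate and defence WRKY list was higher as a set, with 2 of 13 measured members called over all genes and 7 adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 2.55e-08, and adjusted p = 0.28 with an estimated correlation). In the jasmonate list 20 of 21 members had positive values, 1 was called and 9 passed adjusted over the list alone (median 0.37, adjusted p = 3.67e-08, and adjusted p = 0.438 with an estimated correlation). The general phenylpropanoid list was higher too (12 of 15 members positive, none called, 3 adjusted over the list alone, adjusted p = 0.00036, and adjusted p = 0.514 with an estimated correlation). The nitrogen and iron deficiency lists were lower, with negative values in all 12 and all 10 members, none called, and 0 and 1 adjusted over the list alone (medians -0.53 and -0.21, adjusted p = 0.00051 and 0.0169). With an estimated correlation these became adjusted p = 0.514 and 0.676. The iron list lost its call without mock replicate 1 (adjusted p = 0.0824) or BABA replicate 1 (0.0892). WRKY45 (Os05g0322900), a central regulator of defence downstream of salicylate in rice, was at 1189 ± 31.2 normalised reads against 889 ± 38.8 (0.42 ± 0.10, adjusted p = 0.084). Outside the lists and among genes with a mean of at least 20 whose groups did not overlap, Os02g0719600 rose most (2.77 ± 0.28, adjusted p = 0.000321) and Os04g0412500 fell most (-1.38 ± 0.23, adjusted p = 0.0186). The count of 46 was 2 without mock replicate 1, 5 without BABA replicate 2, 9 without BABA replicate 1, 21 without mock replicate 2 and 98 without BABA replicate 3. WRKY76 passed whichever of the 6 libraries was left out, whereas WRKY62 and JAR1 did not pass without mock replicate 1 (adjusted p = 0.133 and 0.152), BABA replicate 1 (0.0591 and 0.0864) or BABA replicate 2 (0.103 and 0.131).

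The comparison of ASM with mock asked the same of the salicylate analogue. WRKY62 rose 5.86-fold to 161.5 ± 8.92 normalised reads (log2 fold change 2.55 ± 0.21, adjusted p = 9.33e-06) and WRKY76 4.92-fold to 529 ± 36.1 (adjusted p = 1.64e-07). WRKY45 rose 1.89-fold from 889 ± 38.8 to 1682 ± 34.6 (0.92 ± 0.10, adjusted p = 5.71e-05), and WRKY71 (Os02g0181300) 1.52-fold (adjusted p = 0.0187). In the salicylate and defence WRKY list 4 of 13 members were called and 7 adjusted over the list alone (median 0.53, adjusted p = 9.4e-08, and adjusted p = 0.28 with an estimated correlation). NPR1 (Os01g0194300), a salicylate co-activator, was at 456 ± 19.6 against 318.5 ± 51.4 normalised reads and did not pass (0.53 ± 0.17, adjusted p = 0.0928). Neither did the pathogenesis-related gene PR1a (Os07g0129200), at 7815 ± 2491 against 3476 ± 1185 (1.17 ± 0.36, adjusted p = 0.0792). PR1b (Os01g0382000) had a mean of 0.364 normalised reads with ASM and 0 in the other groups, all under the 3 reads taken as the floor. The chitinase gene Cht8 (Os10g0542900) rose 1.53-fold (adjusted p = 0.0383), the 1 of 13 pathogenesis-related members called over all genes and 1 of 2 adjusted over the list alone. That list as a set did not pass (adjusted p = 0.211). Without mock replicate 1 WRKY71 had an adjusted p of 0.108, its highest with a library left out, and Cht8 lost its call without mock replicate 1 or 3 or ASM replicate 1 or 2 (adjusted p 0.106 to 0.166).

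Jasmonate genes also rose with ASM, 7 of 21 over all genes and 11 adjusted over the list alone (median log2 fold change 0.52, adjusted p = 2.58e-09, and adjusted p = 0.438 with an estimated correlation). They included the oxophytodienoate reductase gene OPR1 (Os06g0216300) at 2.52-fold (1.33 ± 0.18, adjusted p = 0.000384), JAR1 at 1.87-fold (adjusted p = 0.000165), the allene oxide cyclase gene AOC (Os03g0438100, log2 fold change 0.63) and the transcription factor gene MYC2 (Os10g0575000, 0.52). Of the general phenylpropanoid list 5 of 15 members rose (7 adjusted over the list alone, median 0.65, adjusted p = 1.41e-05, and adjusted p = 0.438 with an estimated correlation). These were PAL2 (Os02g0626400), PAL3 (Os02g0626600), PAL4 (Os02g0627100) and PAL6 (Os04g0518400), which encode phenylalanine ammonia-lyases, the entry enzymes of the pathway, and the coumarate ligase gene 4CL3 (Os02g0177600). PAL4 rose 2.05-fold (1.04 ± 0.15, adjusted p = 0.000959) and PAL3 2.01-fold (adjusted p = 0.00652), values that are uncertain because near copies of a PAL gene can share reads. ACO1 (Os09g0451000, 3.07-fold), which encodes an ethylene-forming oxidase, was higher too. So were the abscisic acid biosynthesis gene NCED5 (Os12g0617400, 3.26-fold), the starvation-induced amylase gene RAmy3D (Os08g0473900, 3.54-fold) and the kinase gene CIPK15 (Os11g0113700, 1.59-fold). The ethylene, abscisic acid and anaerobic lists that hold these genes did not pass as sets (adjusted p = 0.31, 0.265 and 0.446).

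Of the nitrogen and iron lists, 1 gene each was called lower with ASM. The nitrate reductase gene NIA1 (Os08g0468100) fell by 1.25 and the iron regulator gene IRO3 (Os03g0379300) fell by 1.12 on the log2 scale (adjusted p = 0.00285 and 0.00333). Their lists were lower, with 1 of 12 and 1 of 10 members called and 3 and 7 adjusted over the list alone (adjusted p = 0.00703 and 2.01e-05). The aquaporin list was lower with 0 of 9 called and 5 adjusted over the list alone (median -0.31, adjusted p = 0.000427). With an estimated correlation the adjusted p were 0.632 for nitrogen, 0.514 for iron and 0.438 for aquaporins. The nitrogen list lost its call without mock replicate 2 (adjusted p = 0.151) or ASM replicate 2 (0.135). In the iron list ASM replicate 1 stood apart: the iron transporter gene IRT1 (Os03g0667500) had 11710, 4592 and 4404 normalised reads in ASM replicates 1, 2 and 3 against 9909 to 12170 in mock, and the transporter gene YSL15 (Os02g0650300) 12460, 5790 and 6496 against 10760 to 13060. This library was also the highest of its group in most nitrogen genes, and the glutamine synthetase gene GS1;2 (Os03g0223400) had 6350, 3289 and 4140 against 5809 to 8284. Outside the lists and within the same limits of mean and overlap, Os10g0515900 rose most, from 2.79 ± 1.29 to 121 ± 42.2 normalised reads (5.02 ± 0.61, adjusted p = 0.000165), and Os03g0725200 fell most (-2.02 ± 0.22, adjusted p = 7.7e-05). The count of 830 was 366 without mock replicate 1, 400 without ASM replicate 3, 528 without mock replicate 3 and 394 when only the 6 libraries were fitted. Of 21 list genes named as called, 12 passed whichever library was left out. NCED5 did not pass without mock replicate 1 or ASM replicate 3 (adjusted p = 0.127 and 0.116), nor CIPK15 without mock replicate 1 or 3 (0.0613 and 0.0553). ACO1 did not pass without mock replicate 1 or 3 or ASM replicate 2 or 3 (0.0724 to 0.167), nor PAL6 without mock replicate 1 or ASM replicate 2 or 3 (0.066 to 0.0891). PAL2 did not pass without mock replicate 1 or 3 or ASM replicate 1 or 3 (0.0636 to 0.169), and 4CL3 passed only when mock replicate 2 was the library left out (0.0573 to 0.117 without the others).

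**Figure D2:**
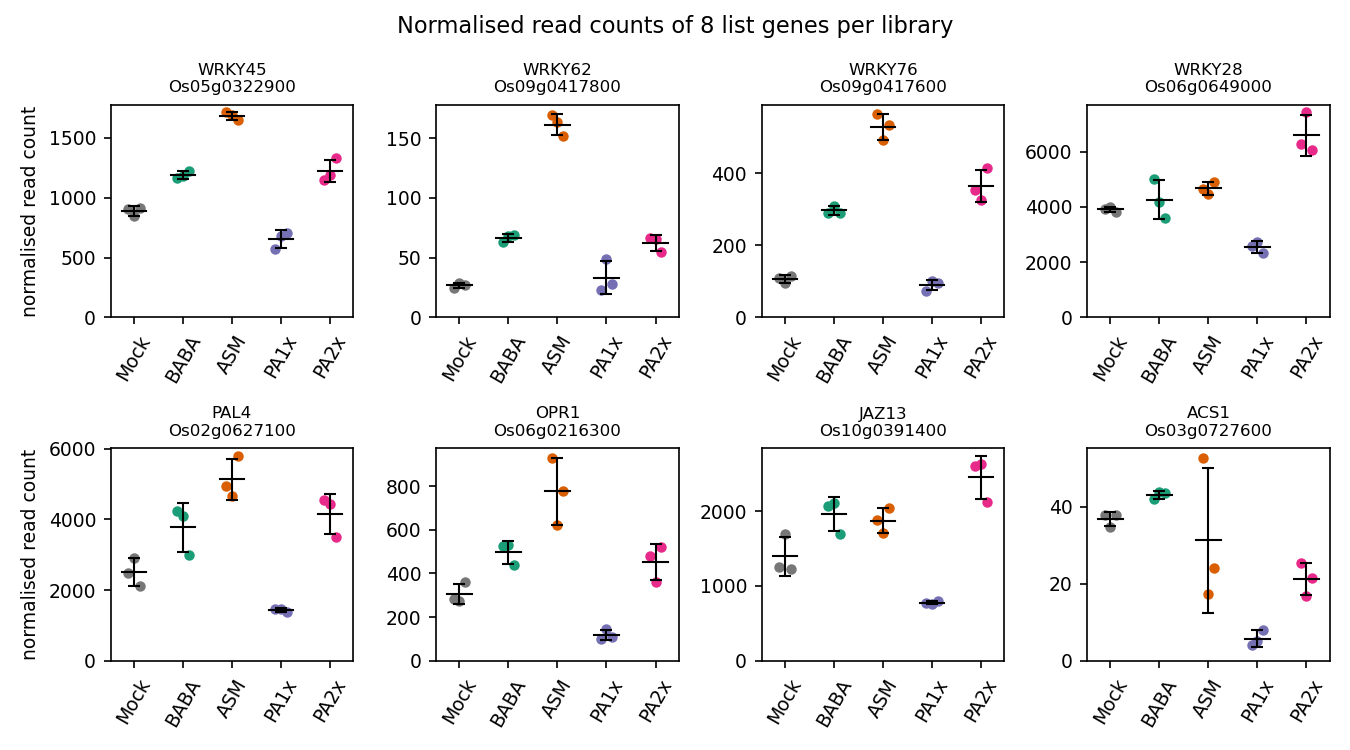
Normalised read counts (linear axes from 0) of 8 list genes in the 15 libraries, with points for libraries, horizontal lines for group means and bars for 1 SD (n = 3). WRKY62 reached a mean of 161.5 with ASM against 26.8 in mock, and ACS1 had a mean of 5.78 with PA1x against 36.8 in mock.

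A single PA spray was followed by lower expression in roots 1 day later. ACS1 (Os03g0727600), which encodes an aminocyclopropane carboxylate synthase of ethylene biosynthesis, went from 36.8 ± 1.77 to 5.78 ± 2.13 normalised reads (log2 fold change -2.52 ± 0.33, adjusted p = 0.000565). OPR1 fell by 1.38 on the log2 scale, from 306 ± 46.3 to 117 ± 23.2 (adjusted p = 0.000565). In the salicylate and defence WRKY list 12 of 13 members had negative values, 6 were called and 7 passed adjusted over the list alone (median -0.47, adjusted p = 2.02e-06, and adjusted p = 0.353 with an estimated correlation). WRKY45 fell by 0.45 (SE 0.10, adjusted p = 0.0148), WRKY28 (Os06g0649000) by 0.62 (adjusted p = 0.00989), WRKY74 (Os09g0334500) by 0.72 (adjusted p = 0.00417) and WRKY70 (Os05g0474800) by 0.98 (adjusted p = 0.0163). In the jasmonate list 5 of 21 members fell, also 5 adjusted over the list alone (median -0.57, adjusted p = 1.41e-05, and adjusted p = 0.514 with an estimated correlation). With the position of each library on the shared axis of replicate spread as a covariate, this median was -0.275. Among them were the JAZ repressor genes JAZ13 (Os10g0391400, -0.83 ± 0.13, adjusted p = 0.00222) and JAZ6 (Os03g0402800, adjusted p = 0.00549) and the list member Os03g0181100 (-0.68 ± 0.14, adjusted p = 0.0121).

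The phenylpropanoid pathway, whose enzyme cinnamate 4-hydroxylase (C4H) PA inhibits, was lower in PA1x, with 5 of 15 members called and, adjusted over the list alone, 6 lower and 1 higher (median -0.34, adjusted p = 0.0068, and adjusted p = 0.574 with an estimated correlation). PAL3, PAL4 and PAL6 fell by 0.84, 0.79 and 0.75 on the log2 scale (adjusted p = 0.0229, 0.00749 and 0.00729). The C4H gene C4H1 (Os05g0320700) stood at 1511 ± 189 normalised reads against 1798 ± 640.1 (adjusted p = 0.888), and C4H4 (Os02g0467600) at 258 ± 24.97 against 610 ± 271.5 (-1.14 ± 0.37, adjusted p = 0.135). C4H3 (Os02g0467000) passed at 1.87 ± 1.21 against 8.04 ± 2.82 normalised reads (adjusted p = 0.0404), with PA1x replicates 2 and 3 under the floor of 3 reads and replicate 1, at 3.22, above it. C4H2 (Os01g0820000) had no read in any of the 15 libraries, which allows up to 3 reads per library. PAL1 (Os02g0626100), the most abundant PAL gene, had means of 34170 ± 551 in mock and 38890 ± 1536 in PA1x (0.19 ± 0.14, adjusted p = 0.722). The catalase gene CatA (Os02g0115700) rose 2.61-fold (1.39 ± 0.26, adjusted p = 0.00671), the secondary wall cellulose synthase gene CESA7 (Os10g0467800) rose 1.64-fold (adjusted p = 0.0455), and ABA8ox1 (Os02g0703600), which degrades abscisic acid, fell by 0.86 on the log2 scale (adjusted p = 0.00374). The ethylene and nitrogen lists were lower, with 1 of 7 and 0 of 12 members called and 1 and 0 adjusted over the list alone (adjusted p = 0.0225 and 0.0499). The aquaporins were higher with 0 of 9 called and 0 adjusted over the list alone (adjusted p = 0.0253). With an estimated correlation these adjusted p were 0.438, 0.676 and 0.551. Outside the lists and within the same limits of mean and overlap, Os10g0165300 rose most (1.68 ± 0.39, adjusted p = 0.0234) and Os03g0313300 fell most (-2.36 ± 0.35, adjusted p = 0.00117).

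For PA1x against mock, ACS1, OPR1, JAZ13, JAZ6, PAL4, PAL6, WRKY74, CatA and ABA8ox1 passed whichever of the 6 libraries was left out. With reads thinned to the smallest library, PAL6, WRKY45 and C4H3 did not pass (adjusted p = 0.198, 0.102 and 0.506), nor did PAL6 without all libraries numbered 3 (0.0575). WRKY45 did not pass without mock replicate 1 or 3 or PA1x replicate 1 (adjusted p = 0.0653, 0.05 and 0.101), nor WRKY28 without PA1x replicate 3 (0.063, its highest). WRKY70 and PAL3 did not pass without mock replicate 1 or 2 or PA1x replicate 1 or 3 (0.058 to 0.0958 and 0.0781 to 0.142), nor Os03g0181100 without mock replicate 2 or PA1x replicate 1 or 3 (0.0565 to 0.0722). C4H3 passed only without PA1x replicate 1 (0.0648 to 0.201 otherwise) and CESA7 only without mock replicate 3 (0.0873 to 0.224 otherwise). The nitrogen list lost its call without each library but mock replicate 3 (0.0506 to 0.341), the aquaporin list without mock replicate 1 (0.156) or PA1x replicate 3 (0.224), and the ethylene and phenylpropanoid lists without mock replicate 2 (0.198 and 0.0543). The count of 646 was 313, 373 and 371 without PA1x replicate 1, 2 or 3, and 406 and 340 without mock replicate 1 or 2.

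With the additional spray on day 7, several of these genes were higher than in mock. In PA2x, WRKY76 rose to 364 ± 44.9 normalised reads from 107 ± 10.3 (log2 fold change 1.76 ± 0.13, adjusted p = 9.02e-06), WRKY62 rose 2.28-fold (adjusted p = 0.0118), WRKY28 1.68-fold (adjusted p = 0.0102) and WRKY45 1.37-fold to 1222 ± 94.2 (0.46 ± 0.10, adjusted p = 0.0353). In the salicylate and defence WRKY list 12 of 13 members had positive values, with 4 called and 10 adjusted over the list alone (median 0.50, adjusted p = 1.23e-10, and adjusted p = 0.266 with an estimated correlation). All 21 jasmonate members had positive values, with 3 called and 9 adjusted over the list alone (median 0.53, adjusted p = 2.61e-10, and adjusted p = 0.438 with an estimated correlation). The called ones were JAZ13 (0.82 ± 0.13, adjusted p = 0.00949), JAR1 (0.74 ± 0.11, adjusted p = 0.00352) and AOC (0.53 ± 0.11, adjusted p = 0.0262). PAL4 rose 1.66-fold (adjusted p = 0.0321), the 1 called member of a phenylpropanoid list with 13 of 15 values positive (adjusted over the list alone 7 higher and 1 lower, median 0.61, adjusted p = 7.97e-05, and adjusted p = 0.482 with an estimated correlation). NAR2.1 (Os02g0595900), partner of the high-affinity nitrate transporters, fell by 1.19 on the log2 scale from 5354 ± 1642 to 2406 ± 931 normalised reads (adjusted p = 0.0478). The nitrogen list was lower with 1 of 12 called and 7 adjusted over the list alone (median -0.89, adjusted p = 7.93e-06), and the iron deficiency list with 0 of 10 called and 0 adjusted over the list alone (median -0.42, adjusted p = 0.000134). With an estimated correlation these became adjusted p = 0.438 and 0.514. In the iron list PA2x replicate 2 stood apart: IRT1 had 9301, 4702 and 8565 normalised reads in PA2x replicates 1, 2 and 3, and YSL15 10980, 6296 and 9941. The asparagine synthetase gene AS1 (Os03g0291500) was at 162 ± 96.0 against 309 ± 75.9 and did not pass (adjusted p = 0.153). PA2x replicate 2 was also the lowest of its group in most nitrogen genes: NAR2.1 had 3358, 1497 and 2363 normalised reads in replicates 1, 2 and 3 and AS1 260.7, 68.98 and 155.6.

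In PA2x the pathogenesis-related list was higher (adjusted p = 0.0341, and adjusted p = 0.687 with an estimated correlation), with Cht8 the 1 member of 13 called over all genes and adjusted over the list alone (1.65-fold, adjusted p = 0.0406). PR1a was at 4902 ± 1897 against 3476 ± 1185 (adjusted p = 0.673). This list lost its call without mock replicate 3, PA2x replicate 1 or PA2x replicate 2 (adjusted p = 0.673, 0.161 and 0.338). Light-harvesting and Rubisco genes, fixed as markers of green tissue, were lower as a list (median -1.28, 0 of 9 called and 0 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.676 with an estimated correlation). Their summed counts stood at 376.8 normalised reads in mock replicate 2 and 408.7 in PA1x replicate 2 against 9.55 to 148 in the other libraries, and the list did not pass without mock replicate 2, mock replicate 3 or PA2x replicate 2 (adjusted p = 0.278, 0.0687 and 0.281). Outside the lists and within the same limits of mean and overlap, Os07g0418500 rose most (2.78 ± 0.23, adjusted p = 1.56e-05) and Os12g0594950 fell most (-1.52 ± 0.30, adjusted p = 0.025). The count of 170 was 30 without mock replicate 1, 43 without PA2x replicate 2, 68 without PA2x replicate 1, 94 without mock replicate 3 and 23 when only the 6 libraries were fitted. WRKY76 and JAR1 passed whichever library was left out, JAR1 not with only the 6 libraries fitted (adjusted p = 0.0969), and WRKY45 and Cht8 in none of these 6 fits (adjusted p 0.0689 to 0.137 and 0.0549 to 0.198). Without mock replicate 1 or PA2x replicate 2, JAZ13 (0.074 and 0.0594), WRKY28 (0.0705 and 0.0645), WRKY62 (0.0773 and 0.0645), AOC (0.137 and 0.136) and PAL4 (0.137 and 0.136) did not pass. WRKY62, AOC and PAL4 also failed without PA2x replicate 1 (0.0584, 0.0927 and 0.136), AOC without mock replicate 2 (0.0731) and PAL4 without mock replicate 3 (0.133). NAR2.1 failed without mock replicate 1 or 2 or PA2x replicate 2 or 3 (0.0706 to 0.202).

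**Figure D3:**
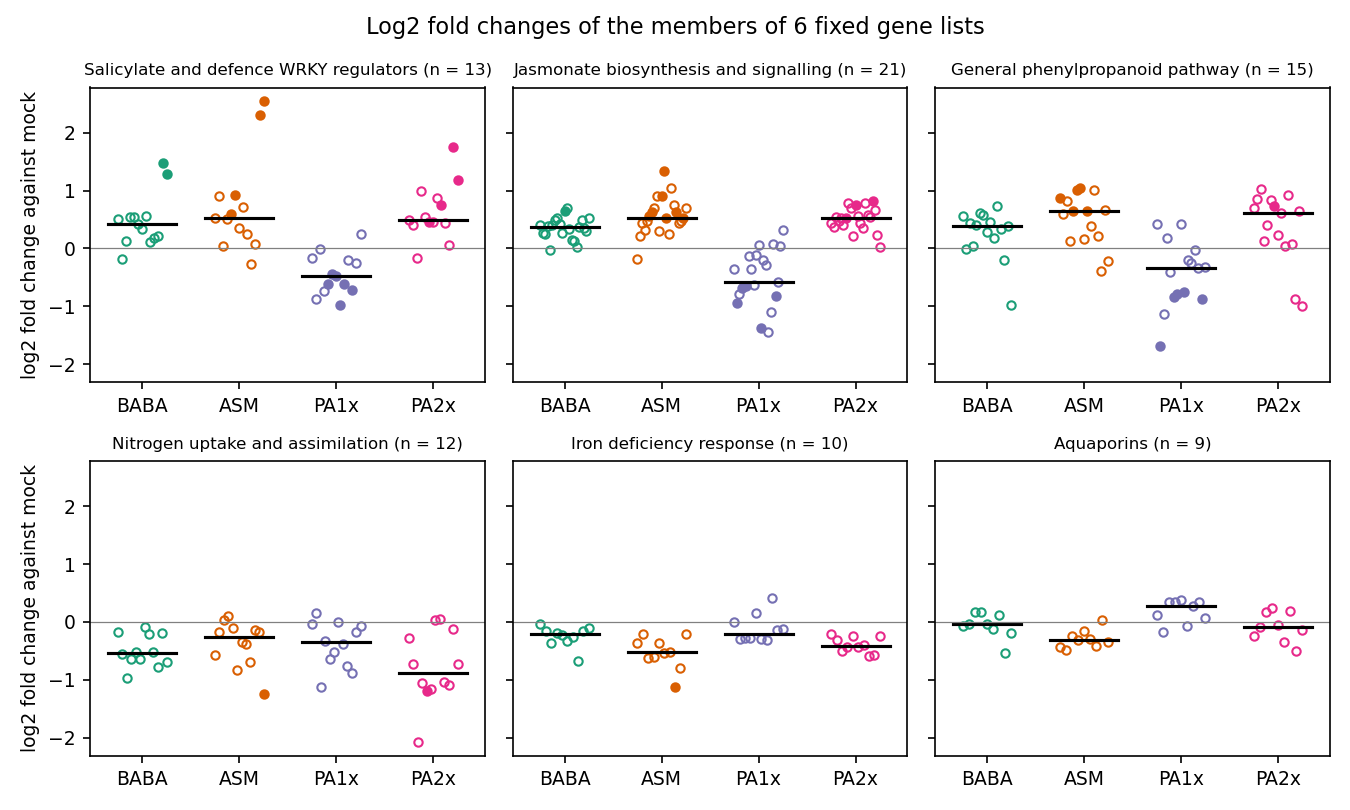
Log2 fold changes against mock of the measured members of 6 gene lists, with filled points for members at an adjusted p under 0.05, open points for the others and horizontal lines for medians. The median of the salicylate and defence WRKY list lies at 0.42, 0.53, -0.47 and 0.50 for BABA, ASM, PA1x and PA2x.

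The direct comparison of PA2x with PA1x tested the effect of the day 7 spray. It gave 2065 genes, 1522 higher and 543 lower in PA2x. WRKY76 was higher by 2.01 ± 0.13 (log2), OPR1 by 1.94 ± 0.18, WRKY70 by 1.85 ± 0.21, JAZ13 by 1.65 ± 0.13, PAL4 by 1.52 ± 0.15 and WRKY45 by 0.91 ± 0.10 (adjusted p between 2.38e-07 and 2.37e-05). The list tests of this comparison were added after the data were examined and were not refitted with libraries left out. They were adjusted within this comparison only, whereas those with mock were adjusted over all comparisons with mock together. In the salicylate and defence WRKY list 12 of 13 members were higher and none lower (camera adjusted p = 6.11e-13, and adjusted p = 0.0448 with an estimated correlation). Before adjustment this camera p with an estimated correlation was 0.00249. For PA2x against mock the same list had 0.00369, which did not pass (adjusted p = 0.266). In the jasmonate list 15 of 21 were higher (6.11e-13, and adjusted p = 0.274 with an estimated correlation) and in the phenylpropanoid list 8 of 15 (7.26e-05, and adjusted p = 0.386 with an estimated correlation). C4H4 was at 1212 ± 400.1 against 258 ± 24.97 normalised reads (2.17 ± 0.37, adjusted p = 0.000791), and the coumarate ligase gene 4CL5 (Os08g0448000) at 2259 ± 567 against 762 ± 26.8 (1.53 ± 0.23, adjusted p = 0.00029). The ethylene list was higher with 3 of 7 called and the aquaporins were lower with 1 of 9 called (adjusted p = 0.036 for both, and adjusted p = 0.386 and 0.572 with an estimated correlation). ACS1 was 3.35-fold higher (adjusted p = 0.00166), and NCED4 (Os07g0154100), an abscisic acid biosynthesis gene, 2.81-fold (adjusted p = 0.000567). IRO3 was lower at 78.6 ± 11.7 against 157 ± 11.7 (-1.001 ± 0.20, adjusted p = 0.00266). NPR1, at 453 ± 90.4 against 281 ± 28.0 (adjusted p = 0.0139), did not pass without PA1x replicate 3 or PA2x replicate 1 or 2 (0.0648 to 0.0764), and the other genes named here passed whichever library was left out. Of the 2065 genes, 601 were also called for PA1x against mock, 149 for PA2x against mock and 1383 for neither.

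PA1x also differed from ASM and from BABA, which had been sprayed on the same day. Against ASM 979 genes were higher and 1898 lower in PA1x, and against BABA 392 were higher and 1393 lower. WRKY76 was lower in PA1x than with ASM (-2.56 ± 0.13, adjusted p = 1.72e-08) and than with BABA (-1.73 ± 0.13, adjusted p = 1.3e-06), and so was OPR1 (-2.71 ± 0.18, adjusted p = 1.07e-07, and -2.09 ± 0.18, adjusted p = 2.36e-06). Of the jasmonate list, 17 of 21 members were lower than with ASM and 12 lower than with BABA (adjusted p = 1.06e-11 and 7.76e-12, and adjusted p = 0.246 and 0.333 with an estimated correlation). Of the salicylate and defence WRKY list 11 and 10 of 13 were lower (1.22e-10 and 4.99e-12, and adjusted p = 0.086 and 0.0534 with an estimated correlation). Of the phenylpropanoid list 8 of 15 were lower in each (1.62e-05 and 3.17e-05, and adjusted p = 0.246 and 0.333 with an estimated correlation). The ethylene list was lower in both, with 3 and 2 of 7 called (0.0139 and 0.0245, and adjusted p = 0.246 and 0.333 with an estimated correlation). Compared with ASM, 6 of 9 aquaporins were higher (7.34e-05, and adjusted p = 0.246 with an estimated correlation), among them TIP1;1 (Os03g0146100) at 5286 ± 394 against 3369 ± 419 normalised reads (0.65 ± 0.11, adjusted p = 0.000673). Iron deficiency genes were higher than with ASM, 3 of 10 called (0.0158, and adjusted p = 0.666 with an estimated correlation), with IRO3 at 1.54 ± 0.20 (adjusted p = 4.12e-05). This list comparison includes ASM replicate 1, which stood apart in IRT1 and YSL15 as given above, and was not refitted without it. Compared with BABA, the abscisic acid list was lower with 3 of 9 called, and the aquaporins were higher with none called (0.048 and 0.0485, and adjusted p = 0.333 and 0.679 with an estimated correlation). PR1a was lower in PA1x than with ASM (-1.22 ± 0.36, adjusted p = 0.0277), a call lost without ASM replicate 2 or 3 or PA1x replicate 1 or 3 (0.0538 to 0.137). The glucanase gene Gns1 (Os05g0375400) of the same list was higher, at 1148 ± 135.5 against 513 ± 141 (1.19 ± 0.33, adjusted p = 0.0222), a call lost without ASM replicate 1 or 2 or PA1x replicate 2 or 3 (0.0563 to 0.0857). The pathogenesis-related list as a set did not pass (adjusted p = 0.603).

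ASM and BABA differed in 55 genes, 39 of them higher with ASM. They included WRKY62 (1.26 ± 0.21, adjusted p = 0.0175), WRKY76 (0.83 ± 0.13, adjusted p = 0.0157) and WRKY45 (0.50 ± 0.10, adjusted p = 0.0397), and no other list member passed. The salicylate and defence WRKY list as a set did not pass (adjusted p = 0.0519). Aquaporins and iron deficiency genes were lower as lists with ASM than with BABA, with no member called (adjusted p = 0.000729 and 0.0122, and adjusted p = 0.761 for both with an estimated correlation). In the iron genes IRT1 and YSL15, ASM replicate 1 stood apart from the other ASM replicates, and the list was not refitted without it. PR1a was at 7815 ± 2491 with ASM against 3435 ± 1373 with BABA, a log2 difference of 1.22 with a 95% interval of 0.46 to 1.98 before adjustment (adjusted p = 0.186). Outside the lists and within the same limits of mean and overlap, Os10g0515900 was highest (3.45 ± 0.61, adjusted p = 0.0216) and Os01g0304400 lowest (-1.42 ± 0.18, adjusted p = 0.00292) in ASM relative to BABA. WRKY76 did not pass without BABA replicate 1 or ASM replicate 3 (0.0656 and 0.101). WRKY62 did not pass without BABA replicate 1 or 2 or ASM replicate 2 or 3 (0.064 to 0.101), and WRKY45 passed only without ASM replicate 1 (0.0771 to 0.168 otherwise). The count of 55 was 267 without ASM replicate 1, with 105 higher and 162 lower, and without all libraries numbered 3 it was 46, with 16 higher and 30 lower, so that the majority lay on the other side in both. It was 12 and 7 without ASM replicates 2 and 3, and 23, 17 and 31 without BABA replicates 1, 2 and 3.

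Overlaps between the 4 comparisons with mock were set beside 100 simulations of unchanged groups. Each dealt the deviations of the 15 libraries from their group means at random into 5 groups. In each, 1 group stood for the shared mock, so the real mock libraries were not kept together. WRKY62, WRKY76 and JAR1 were among 27 of the 40 genes higher with BABA that were also higher with ASM and in PA2x. ASM and PA2x had 96 genes higher in common and 12 lower, against 4.59 and 0.377 for independent lists of the same length and 0 and 0 in the simulations, in which almost no gene is called, so that they give no overlap to expect from the shared mock. BABA and ASM shared 38 genes higher and 4 lower (independent lists 1.31 and 0.0753), and BABA and PA2x 28 and 4 (0.306 and 0.00983). ASM and PA1x moved 193 genes in opposite directions, 178 of them higher with ASM and lower in PA1x (independent lists 18.8), and shared 7 higher and 6 lower (2.39 and 7.2). PA1x and PA2x moved 68 genes in opposite directions, 58 of them lower in PA1x and higher in PA2x (independent lists 4.38), and shared 5 higher and 0 lower. Across the 18316 genes, which are not independent replicates, the fold changes of ASM and PA2x correlated at 0.539 (simulated 0.519) with a covariance of 0.0809 (simulated 0.0527). Those of PA1x and PA2x correlated at 0.0167 (simulated 0.521) with a covariance of 0.00217 (simulated 0.0524). The covariance of BABA was 0.0758 with ASM and 0.0673 with PA2x (simulated 0.0507 and 0.0503) and 0.00747 with PA1x (simulated 0.0513), and that of ASM and PA1x was -0.011 (simulated 0.0504). Over the 100 simulations the correlations spread widely. The measured correlation of ASM and PA2x lay inside its simulated limits (0.103 to 0.831). So did those of BABA with ASM (0.551, limits 0.112 to 0.761), PA2x (0.557, 0.0477 to 0.824) and PA1x (0.0627, 0.0572 to 0.842). Those of PA1x with PA2x (limits 0.162 to 0.774) and with ASM (-0.0742, 0.0544 to 0.797) lay below theirs. The simulations held no real changes and mixed libraries of groups with unequal spread. A correlation below the limits can therefore come from unrelated changes as well as from opposite ones. The covariances have no such limits here. The 3 mock libraries were too few to be split, and part of any excess can come from the shared mock. In all, 136 genes were called in the same direction in at least 2 of the 4 comparisons, a count of 22 without mock replicate 1, 68 without PA2x replicate 1 and 63 without PA2x replicate 2.

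Replicates of a group were spread along a shared axis. The first component of the deviations from the group means held 29.6% of their variance, against 12.2% and 10.2% for the next components. The members of the diterpenoid phytoalexin list had a median correlation of 0.953 with this axis over the 15 libraries, the pathogenesis-related list 0.927, the jasmonate list 0.905, the flavonoid list 0.877, the phenylpropanoid list 0.816, the salicylate and defence WRKY list 0.603 and the lignin list 0.582. It was -0.685 for the clock, -0.606 for the aquaporins and -0.539 for the iron deficiency list. The median absolute loading of the salicylate and defence WRKY list was 0.00356, against 0.0036 over all genes tested, 0.00712 in the jasmonate, 0.00792 in the phenylpropanoid, 0.0193 in the pathogenesis-related and 0.0376 in the diterpenoid phytoalexin list. CPS4 (Os04g0178300), a diterpene cyclase gene of momilactone synthesis, ranged from 382 to 1531 normalised reads within ASM and from 389 to 1896 within PA2x. Libraries numbered 3 lay lowest on the axis in mock, BABA, PA1x and PA2x, and ASM replicate 3 lay highest in its group.

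**Figure D4:**
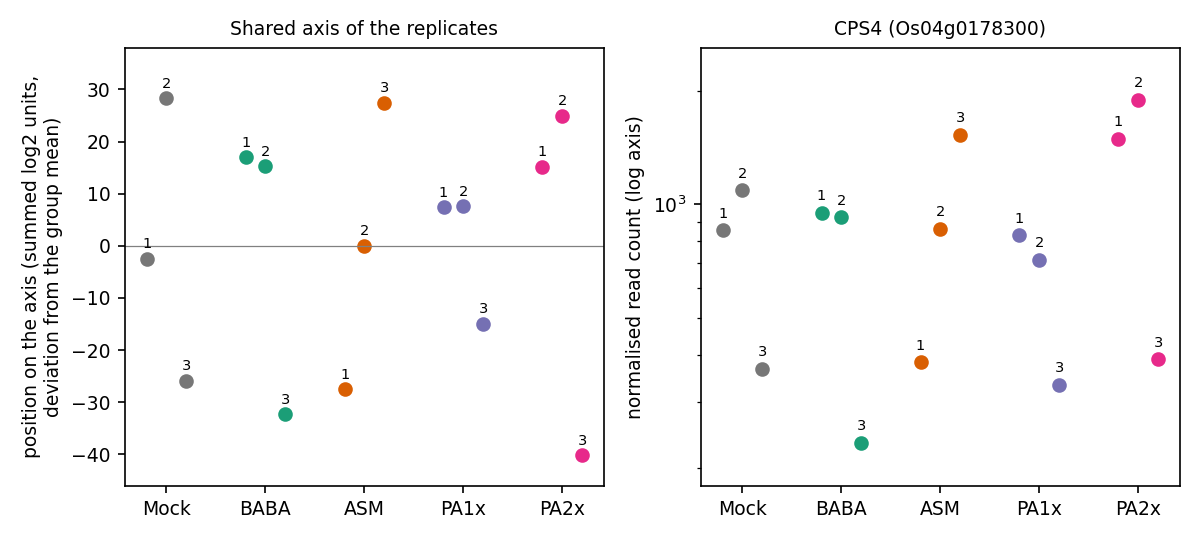
Position of each library on the axis as the deviation from its group mean in summed log2 units (left), and normalised read count of CPS4 on a log axis (right), with points for libraries and their replicate numbers above. Positions run from -40.2 in PA2x replicate 3 to 28.3 in mock replicate 2.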

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

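The tests with thinned reads, with axis position and of the clock genes in this part were chosen after the results were seen.

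In 4 list genes called against mock in both PA groups, the fold changes had opposite signs. The genes were picked for these opposite calls against 1 shared mock, so a called difference between the PA groups was close to fixed in advance (68 of 68 such genes had it) and adds no separate evidence. PA2x minus PA1x was 1.52 on the log2 scale for PAL4, 1.65 for JAZ13, 0.91 for WRKY45 and 1.37 for WRKY28 (n = 3 per group). Their adjusted p for this difference were 7.23e-06, 1.3e-06, 1.2e-05 and 3.56e-06, and all 3 PA2x libraries lay above all 3 PA1x libraries in each.

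PA2x and PA1x differed in 2065 genes, more than either differed from mock. With all libraries thinned to the smallest, 1607 genes still differed, which argues against depth as the whole cause. With axis position as a covariate, group means included, 2531 genes differed. Counts with this covariate also rose elsewhere, from 46 to 542 for BABA and from 55 to 414 for ASM and BABA. The count therefore does not weigh against the axis. The median difference of the salicylate and defence WRKY list went from 0.946 to 0.914 and that of the jasmonate list from 1.15 to 0.848. For these 2 lists this argues against the shared axis as the whole cause. The median absolute difference of the clock genes was 0.194, at percentile 42.01 of 10000 random lists (random median 0.212), so another time of day at harvest cannot be told apart from other sources, since the random lists came from the same comparison and the value lay within their spread. The spray schedule stays open, since PA2x differed from PA1x by a spray on day 7 and no mock group had that spray, and an effect of PA itself is a hypothesis that these data cannot separate from the schedule.

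For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with the most genes in each: 46 for BABA (highest other 2), 830 for ASM (5), 646 for PA1x (0), 170 for PA2x (0), 2065 for PA2x and PA1x (0), 2877 for PA1x and ASM (0), 1785 for PA1x and BABA (0) and 55 for ASM and BABA (1). For gene lists, 4 of 10 splits gave as many lists as the real 5 for BABA (highest other 6), 3 of 10 as many as the 6 for ASM (highest other 7), 3 of 10 as many as the 6 for PA1x (highest other 10) and 3 of 10 as many as the 7 for PA2x (highest other 7). The number of lists passing camera with the preset correlation therefore did not set the real grouping apart from other splits. Over all 15 libraries, the real split was the 1 of 100 that gave as many genes as 2227, with 1061 as the highest other. A random split is thus an unlikely source of that count, though 100 splits cannot exclude it. The splits do not bear on a batch.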

How the results depend on the processing

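Tests with the axis covariate, thinned reads and all libraries numbered 3 left out were chosen after the results were seen. No named gene, and no list in a comparison with mock, reversed in the settings run, but genes differing between ASM and BABA went from 39 higher and 16 lower to 105 and 162 without ASM replicate 1 and to 16 and 30 without the libraries numbered 3. List tests of the direct comparisons were not refitted. With an estimated correlation 0 lists passed in each comparison with mock, and 1, 1, 1 and 2 had an unadjusted p under 0.05 for BABA, ASM, PA1x and PA2x. The lowest and highest values with 1 library left out were 2 to 98 genes for BABA, 366 to 879 for ASM, 313 to 618 for PA1x, 30 to 243 for PA2x, 7 to 267 for ASM and BABA, and 22 to 200 for the overlap of calls. They were 1385 to 2327 for PA2x and PA1x, 2025 to 2783 for PA1x and ASM, 1193 to 1870 for PA1x and BABA and 1543 to 2498 for the F test. List counts ran from 5 to 7 for BABA, 5 to 8 for ASM, 4 to 7 for PA1x and 5 to 8 for PA2x. BABA gave 86 genes at a mean of at least 20, where fewer genes are tested, and 89 with TMM, whose median shifts were all under 0.01 in size. With only the 6 libraries the counts were 10 for BABA, 394 for ASM, 23 for PA2x, 19 for ASM and BABA and 24 for the overlap. They rose to 856 for PA1x, 3170 for PA1x and ASM and 1940 for PA1x and BABA. DESeq2 gave 201, 375 and 173 for BABA, PA2x and ASM and BABA, and 340 for the overlap. The axis covariate, which by its construction is the same on average in every group and removes spread only, gave 529, 1817, 1394 and 1044 for BABA, ASM, PA1x and PA2x. It gave 3250 for PA2x and PA1x, 2760 for PA1x and BABA, 566 for ASM and BABA, 4076 for the F test and 794 for the overlap. Without the libraries numbered 3, ASM gave 503. For the 6 libraries, TMM and DESeq2 the cause was not tested. The main fit pools the spread of a gene over all 5 groups, and the groups were not equally spread. On the shared axis the SD was 12.94 in PA1x, 27.18 in mock, 27.99 in BABA, 27.48 in ASM and 35.15 in PA2x. The next tallies cover named single genes and the lists that had passed. Lists newly passing are not in them, though the list counts above rose in some fits. Calls were lost 213 times and gained 8 times with 1 library left out, 28 and 4 times with only the 6 libraries, 31 and 4 times without the libraries numbered 3 and 21 and 1 times with thinned reads. They were lost 16 times with no filter, 4 times with edgeR and 2 times with a pseudocount of 5. DESeq2 lost 2 and gained 5, and the axis covariate lost 1 and gained 25. Lists defined by gene descriptions were not run.

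The replicate numbers did not meet the rule for pairing, that every same-number pair correlates over 0.1: 9 of 30 did (-0.339 to 0.4), with medians of 0.0055, 0.0863 and 0.239 for numbers 1, 2 and 3, and 8 of 15 libraries correlated best with their own number. With the replicate number as a block the counts were 63 for BABA, 864 for ASM, 687 for PA1x, 190 for PA2x, 2177 for PA2x and PA1x, 2988 for PA1x and ASM, 1873 for PA1x and BABA and 61 for ASM and BABA. Among named results the block ended the calls of Cht8 with ASM (adjusted p = 0.0522) and in PA2x (0.0568), CESA7 in PA1x (0.0607), HRZ1 between PA1x and ASM (0.0545) and the nitrogen list in PA1x (0.0524). NPR1 and PR1a with ASM (0.034 and 0.0324) and PAL3 in PA2x (0.0341) passed with it, and it changed no other call.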

Other observations

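The tests of the replicate axis in this part were chosen after the axis was seen.

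Diterpenoid phytoalexin genes, which make the momilactones and phytocassanes of rice, did not pass as a list in any comparison with mock (lowest adjusted p = 0.135, in PA2x). In PA1x all 15 measured members had negative log2 fold changes, and in PA2x 14 of 15 had positive ones, with none called. The lignin and secondary wall list had its lowest adjusted p of 0.0805 in PA1x. There 4 members were higher and 1 lower adjusted over the list alone, with CESA7 called. The other lists that did not pass with camera were the abscisic acid list (lowest adjusted p = 0.135), the reference genes (0.178), the antioxidant and circadian clock lists (0.443 for both) and the anaerobic, flavonoid and phosphate starvation lists (0.446 for each). Median, mean and test differed in sign for the anaerobic list with BABA and ASM, the antioxidant list with BABA and ASM, the flavonoid list with BABA, and the clock and phosphate lists in PA1x, none of which passed.

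Replicates of a group were spread along 1 axis that held 29.6% of the within-group variance. The reads argue against depth as its whole cause: log2 reads and axis position within groups correlated at r = -0.158 (exact permutation p = 0.639) and rho = -0.2 (exact permutation p = 0.559) over 15 libraries, and r was 0.192 without BABA replicates 3 and 1. So few libraries cannot exclude that depth had a part in it. A batch marked by the replicate number may account for part of the spread: numbers held 36% of the axis variance, against a median of 16.4% over 7776 orderings (exact permutation p = 0.175), and too few libraries keep this open. Another time of day at harvest cannot be told apart from other sources either, since the median absolute loading of the clock genes lay at percentile 92.28 of 10000 random lists, above their median and below the 95th percentile set for it. No biological explanation was tested, because the labels give no plant or pool data beyond the group.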
